A study of Mus musculus with 20 samples.

How the data were processed

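Footprints were measured in 20 libraries of mouse embryonic fibroblasts, 12 from Ribo-seq and 8 from eIF3-80S-seq. Per the labels' protocols, Ogt was knocked out with 0.5 µM 4-OHT for 24 h followed by fresh medium for 24 h, Thiamet-G was given at 0.1 µM for 16 h, and starvation was 2 h in DMEM with "DFBS", an abbreviation that the labels do not explain. Ribosome fractions from sucrose gradients were digested with RNase I, and fragments were selected on a gel, over a wider range of sizes for eIF3-80S-seq than for Ribo-seq. The authors deposited 1 file per library with a transcript identifier and its RPKM, a read number scaled to transcript length and library total. The submitters' processing notes name cutadapt, STAR and the build GRCm38. The read counter, the annotation release, the choice of transcripts and any filter are not given in the sources used here.

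Groups and replicate numbers came from the titles. The 2 starved Thiamet-G Ribo-seq libraries have opposite replicate numbers in titles and file names. No pair of libraries was a duplicate. The mean chi-square per transcript between replicates was 30.3 to 107 over 6 Ribo-seq pairs and 13.3 to 14.8 over 2 eIF3-80S pairs, far above sampling noise. Some libraries of different groups were closer to each other than any replicates. The lowest value was 11.9 among 60 such Ribo-seq pairs and 3.64 among 26 such eIF3-80S pairs, also above sampling noise.

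Depth was recovered from the RPKM values. Ratios of a transcript's values between libraries fell on fractions of whole numbers within a relative tolerance of 1e-09, which gave whole reads, library totals and a length per transcript for 13278 of 15354 transcripts. At least 96.45% of the values of each library were recovered, and each total lay within 1.6e-08 of a whole number. The lengths are termed coding lengths because 99.78% were multiples of 3. The scale was accepted only if most lengths were such multiples, so a high share was partly required by the procedure. Simulated lengths were multiples of 3 as well. Tested on 4000 simulated transcripts, 99.57% of values came out exactly. Reads on transcripts that a file did not list made up 0.04% to 2.72% of Ribo-seq totals and 3.27% to 32.6% of eIF3-80S totals. The 10 most read transcripts held 4.35% to 7.55% of Ribo-seq reads and 5.92% to 26.1% of eIF3-80S reads. Precision is limited by depth in the eIF3-80S libraries, where the median listed transcript had 9 to 19 reads.

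RPKM values were rescaled between libraries by the median ratio to the geometric mean over transcripts listed in every library of a fit, with an unlisted transcript taken as 0. Transcripts with a mean of at least 1 RPKM were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(RPKM + 1), two-sided, with a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this scale, which understates changes of low transcripts, and RPKM and shares of reads are relative to the library. Ribo-seq contrasts came from 1 fit of 6 groups with 6 residual degrees of freedom. eIF3-80S starvation was tested in a fit of groups, with 2 residual degrees of freedom from the control libraries alone, and in an additive fit of background and starvation with 4. The assays were compared in 1 fit of all 12 groups with 8 residual degrees of freedom. These fits, their alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named targeted and listed genes and, per comparison, called transcripts with non-overlapping libraries and the largest fold changes. Since no identifier could be matched to a symbol (0 in the reference table), that part and all gene lists were left out, and at most 2 identifiers per direction are printed. Transcripts were kept as listed, 1 value per identifier.

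The other steps were chosen after the data were seen. They are limma-voom on recovered reads with at least 10 reads on average, a uniform floor of 5 reads, fits restricted to transcripts listed in every library together with a batch block, the fit without Thiamet-G libraries, the classes of coding length (at most 600 nt and over 3000 nt), sign flips within pairs, reads expected for missing values, and tests of one assay's called transcripts in the other with camera and Fisher's exact test. Limma-voom scaled reads to library totals alone, without the median ratio between libraries. The batches were defined by whether under 1% of transcripts with recovered reads had under 5 reads. Replicate numbers of the file names follow them. Deviations from group means correlated at 0.188 to 0.453 in 15 of 15 pairs of groups, across transcripts. Unlisted transcripts entered these deviations as 0, so the listing that defined the batches may add to the correlations by construction. Its part was not tested. Among transcripts listed in every library, the block raised the averaged starvation calls from 34 to 104. These numbers were taken to pair the Ribo-seq libraries, and the batch block is given beside the results it changed. Exact permutation tests, random lists matched on level (or on level and coding length) and thinning were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Where leaving out a library left 1 in a group, that library was assumed to vary like the others. The fits were tested on simulated libraries with known changes, placed in transcripts above the median level. Simulated noise was independent between transcripts and held no batches. In the additive eIF3-80S fit 0 of 67, 6 of 67 and 7 of 66 changes of 2-fold, 4-fold and 8-fold were recovered among 7734 transcripts, and 53 of 67, 67 of 67 and 66 of 66 among the 1679 listed in every library, with 6 false calls. The averaged Ribo-seq fit made 11 false calls.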

Results

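Ribosome-protected RNA fragments were measured in mouse embryonic fibroblasts (strain C57BL/6J) of 3 backgrounds, namely control cells, cells with a 4-OHT-induced knockout of Ogt, and cells given Thiamet-G. Ogt encodes O-GlcNAc transferase, which attaches N-acetylglucosamine to serine and threonine residues of intracellular proteins, and Thiamet-G inhibits O-GlcNAcase, the enzyme that removes this sugar. Cells of each background were fed or were starved of amino acids for 2 h, a treatment that activates the integrated stress response. The series title places the modification on eIF3a, a subunit of the initiation factor eIF3, so the comparisons ask how starvation and a loss or gain of O-GlcNAc altered the distribution of ribosomes over transcripts. A pair of assays was used. Ribo-seq sampled footprints of all ribosomes and comprised 12 libraries, 2 in each of 6 groups. The other assay, termed eIF3-80S-seq here, sampled footprints of 80S ribosomes associated with eIF3 and comprised 8 libraries, 2 each of fed and starved control cells and 1 each of the other 4 groups. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

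Each file listed Ensembl transcript identifiers with an RPKM above 0. Coding reads, recovered from the steps between RPKM values, ranged from 844403 in starved knockout replicate 2 to 5846130 in starved control replicate 1 for Ribo-seq. The eIF3-80S libraries were far shallower, from 52148 reads in starved control replicate 1 to 359282 in fed Thiamet-G cells. Ribo-seq files listed 9427 to 12197 transcripts and eIF3-80S files 1919 to 7197. Of 15354 transcripts found in any file, 8373 were listed in all 12 Ribo-seq files and 1679 in all 8 eIF3-80S files. Transcripts under 5 reads made up 14.06% to 21.51% of those with recovered reads in 6 Ribo-seq libraries and at most 0.08% in the other 14 libraries, whose files were listed almost wholly from 5 reads. This split put 1 Ribo-seq library of each group in each of 2 processing batches, and the first principal component of the Ribo-seq values, with 28.5% of the variance, separated those batches. Unlisted transcripts were 0 in these values, so the listing itself may add to that separation. The files do not pair transcript identifiers with gene names, so Ogt, Oga, Atf4 and Eif3a, which would have checked the labels, and gene lists of the integrated stress response and translation were not analysed here. Transcripts are therefore described by identifier, level and coding length, which had a median of 1446 nt.

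**Figure D1:**
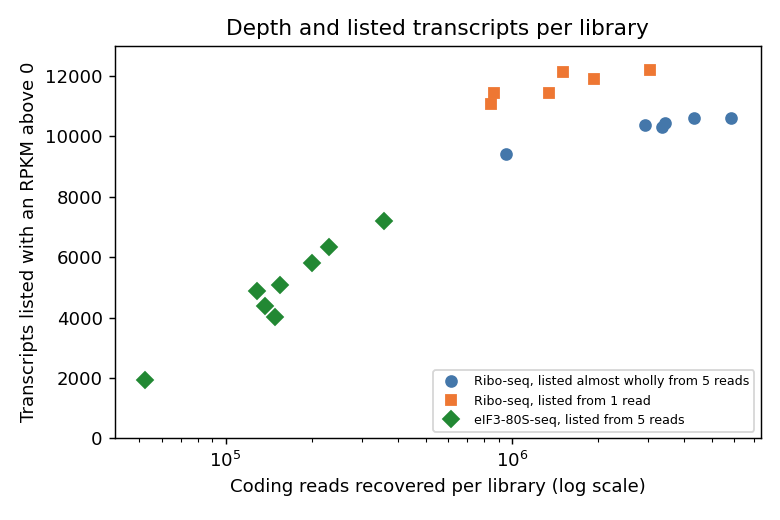
Number of transcripts listed with an RPKM above 0 (vertical axis) against recovered coding reads (horizontal log axis), 1 point per library. The 8 eIF3-80S libraries (diamonds) lie between 52148 and 359282 reads, and the 12 Ribo-seq libraries at 844403 reads or more, with more transcripts listed in the 6 libraries with many transcripts under 5 reads (squares) than in the 6 listed almost wholly from 5 reads (circles).

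Starvation lowered the relative footprint level of a small set of highly read transcripts. In the contrast averaged over the 3 backgrounds, 19 of 10936 transcripts fell, by 3.19-fold to 8.45-fold. These transcripts were among the most heavily read, with a median of 2740 RPKM, and encoded short proteins. Their median coding length was 519 nt, and 13 of the 19 (68.4%) had at most 600 nt, against 13.6% of the 10882 tested transcripts of known coding length (Fisher's exact test, adjusted p = 8.94e-08 over 7 such tests). Among 10000 random lists matched on level, however, 72.11% held as large a share of short coding regions. Such lists, here and below, could draw the called transcripts themselves, which pulls their share towards the observed one. This value therefore does not separate coding length from level for these 19. Limma called 0 transcripts higher in this contrast, where 984 had an unadjusted p under 0.05, and limma-voom on recovered reads called 6 higher and 43 lower. With the processing batch as a block limma-voom called 257 higher and 123 lower, so a predominance of decreases depended on the fit. Limma-voom scaled reads to library totals alone, and the median log2 fold change was 0.090 in its fit with the block, against -0.013 in limma. The part of scaling in this shift was not tested.

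ENSMUST00000008812, with a coding length of 459 nt, had the largest decrease of the 19. It measured 1545 ± 727 RPKM in fed and 184 ± 111 RPKM in starved libraries (SD, n = 6 each), and fell by 3.08 on the log2 scale (SE 0.418, limma adjusted p = 0.0398). Control cells had 2115 ± 261 RPKM when fed and 150.0 ± 24.5 RPKM when starved (n = 2 each). Levels were 807 ± 473 and 233 ± 205 RPKM in knockout cells and 1715 ± 746 and 168 ± 106 RPKM in Thiamet-G cells. ENSMUST00000108428, with a coding length of 639 nt, fell by 2.56 on the log2 scale (SE 0.384, limma adjusted p = 0.0398), from 2613 ± 1340 to 452 ± 256 RPKM (n = 6 each). With the processing batch as a block, limma called 79 transcripts lower, by up to 8.91-fold, and 21 higher, which included all 19. The 79 had a median coding length of 468 nt, and only 0.25% of random lists of the same level held as large a share of coding regions of at most 600 nt (54 of 79, 68.4%). The 21 had a median of 1080 nt, with 2 of at most 600 nt. Under quantile normalization or a pseudocount of 0.1 limma called 0 transcripts, with 974 and 988 at an unadjusted p under 0.05, and leaving out single libraries gave 0 to 25 calls. Of these 12 fits 9 gave 0 by limma, with 781 to 1236 at an unadjusted p under 0.05, and the calls of both transcripts named above ended in them too, with log2 fold changes of -3.31 to -2.73 and -2.72 to -2.24 (limma adjusted p of 0.06 to 0.208).

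Within single backgrounds, where each group held 2 libraries, limma called 0 of 10936 transcripts for starvation. The numbers with an unadjusted p under 0.05 were 744 (6.80%) in control, 653 (5.97%) in Thiamet-G and 99 (0.91%) in knockout cells, and limma-voom on recovered reads also called 0 in each. With the batch as a block in limma-voom, 220 transcripts were called in control cells (119 higher and 101 lower), 13 in Thiamet-G cells and 0 in knockout cells. Changes were also simulated in transcripts above the median level, with independent noise and no batches. The recovery below therefore does not cover transcripts of lower level or noise shared between transcripts. In control cells the fit recovered 0 of 67 transcripts changed 2-fold, 4 of 67 changed 4-fold and 19 of 66 changed 8-fold, whereas the average over backgrounds recovered 6 of 67, 52 of 67 and 63 of 66.

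A lower share of footprints on short coding regions was also seen across all reads of a library. Coding regions of at most 600 nt took 34.2% ± 6.79 of Ribo-seq reads in fed and 25.9% ± 3.76 in starved libraries (SD, n = 6 each), a difference of -8.38 percentage points (two-sided exact permutation p = 0.0238, adjusted p = 0.0381 over 8 tests; p = 0.025 when permuted exactly within batches, and p = 0.0625 by exact sign flips within the 6 pairs of one background and batch, which could not give a p below 0.0312). In control cells the share was 38.9% ± 6.22 fed and 24.1% ± 4.22 starved, and in Thiamet-G cells 36.9% ± 4.40 and 27.1% ± 1.02 (n = 2 each). In knockout cells it was 26.9% ± 2.20 fed and 26.3% ± 6.49 starved (n = 2 each). The difference was -13.1 ± 9.32 points over the 3 pairs of the batch listed from 5 reads, all 3 lower, and -3.63 ± 5.37 points in the other batch, where 2 of 3 were lower and the knockout pair differed by 2.51 points. The response in knockout cells, -0.53 ± 4.29 points (n = 2), could not be distinguished from that in the other backgrounds, -12.3 ± 7.37 points (n = 4), by an exact permutation test (p = 0.133), which could not give a p below 0.0667. Coding regions over 3000 nt took 6.51% ± 1.07 of reads in fed and 8.38% ± 1.42 in starved Ribo-seq libraries (n = 6 each, exact permutation p = 0.0346, adjusted p = 0.0396), and 22.15% and 24.71% in fed and starved eIF3-80S libraries (n = 4 each, exact permutation p = 0.571). The difference on short coding regions missed the threshold without starved control replicate 1 (-7.43 points, exact p = 0.0519) or without starved knockout replicate 1 (-7.55 points, exact p = 0.0519). The length classes were chosen after the data were seen.

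**Figure D2:**
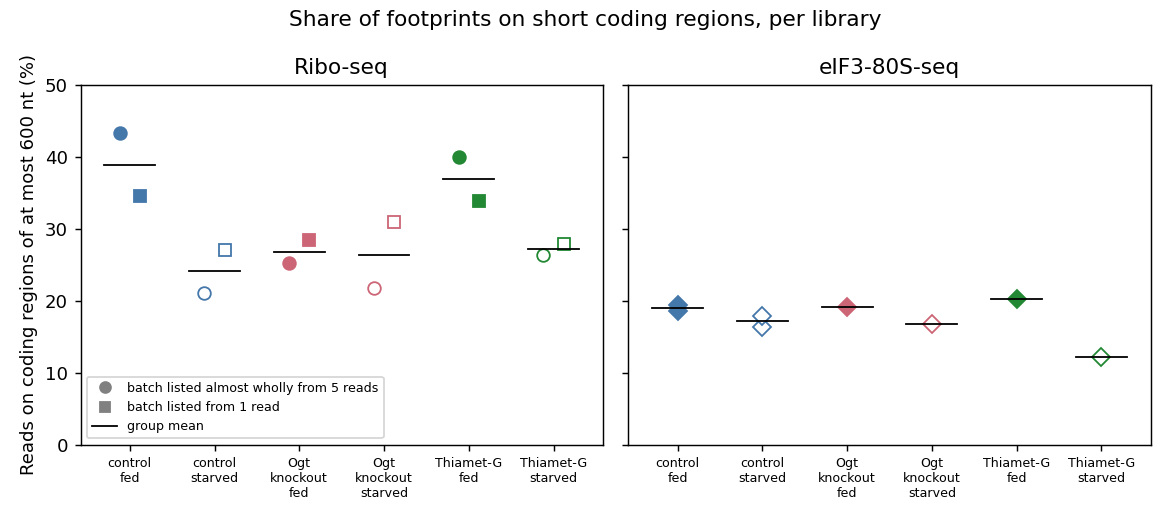
Percentage of recovered coding reads on coding regions of at most 600 nt (vertical axis) in each group, 1 point per library, filled for fed and open for starved, with horizontal lines at group means. Fed control and Thiamet-G Ribo-seq libraries sit highest, with group means of 38.9% and 36.9%, fed knockout libraries have a mean of 26.9%, and every eIF3-80S starved library lies below every fed one.

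The effects of the knockout and of Thiamet-G in fed cells were tested next. The labels give 4-OHT and fresh medium for knockout cells only. Knockout contrasts therefore cannot tell the loss of Ogt apart from that treatment. O-GlcNAc itself was not measured in these libraries. In Ribo-seq, limma called 0 transcripts between knockout and control cells, where 401 of 10936 (3.67%) had an unadjusted p under 0.05, and 0 between Thiamet-G and control cells, where 51 (0.47%) did. The direct contrast of knockout with Thiamet-G cells gave 0 calls and 642 transcripts (5.87%) at that level. Limma-voom on recovered reads called 0 in all 3 contrasts, and with the batch as a block 0, 0 and 21. The 19 transcripts that fell in starvation had a median log2 ratio of fed knockout to fed control of -1.32 in the batch listed from 5 reads and -1.75 in the other, and 19 and 18 of them were below 0. Median ratios of fed Thiamet-G to fed control were -0.017 and -0.022. Because the control libraries compared also entered the starvation contrast that chose these 19 transcripts, the ratios are not independent of that choice. Transcripts called in the eIF3-80S libraries, which share no library with Ribo-seq, gave a set free of it. The 104 called lower there had a median log2 fold change of -0.63 between fed knockout and control Ribo-seq, with 67 of 104 below 0 and medians of -0.48 and -0.62 within the batches (camera with a preset correlation, adjusted p = 4.19e-07 over 42 tests; adjusted p = 0.449 with an estimated correlation). Among random lists matched on level and coding length, the -0.48 lay at the 49.53 percentile and the -0.62 at the 0.00 percentile. The 104 were thus not lower than such lists in the batch listed from 5 reads. The 76 called higher in the eIF3-80S libraries had a median of 0.439, with 54 of 76 above 0. Camera gave them an adjusted p of 0.000987 with a preset and 0.449 with an estimated correlation. Within the batches their medians were 0.449 and 0.487, at the 95.93 and 99.97 percentiles of such lists. The 0.449 lay inside the -0.018 to 0.479 of its matched lists. For Thiamet-G the median of the 104 was 0.028 (camera with a preset correlation, adjusted p = 0.534).

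Whether starvation acted differently in the modified backgrounds was tested as an interaction. Limma called 0 of 10936 transcripts for the interaction with the knockout, with 216 (1.98%) at an unadjusted p under 0.05, and 0 for the interaction with Thiamet-G, with 145 (1.33%). Limma-voom called 0 for both, and 1 and 0 with the batch as a block. The 104 transcripts called lower in the eIF3-80S libraries had a median interaction with the knockout of 0.50 on the log2 scale, a smaller decrease than in control cells (camera with a preset correlation, adjusted p = 0.000225; adjusted p = 0.498 with an estimated correlation). For the 104, the smaller decrease came from 1 batch. In the batch listed from 5 reads the median starvation ratios of the 104 were -1.058 in knockout and -1.073 in control cells. In the other batch they were 0.168 and -0.678. The 76 transcripts called higher in the eIF3-80S libraries had a median interaction with the knockout of -0.650, with 57 of 76 below 0. Camera gave them an adjusted p of 0.000269 with a preset and 0.449 with an estimated correlation. Their median starvation ratios were lower in knockout than in control cells in both batches. They were 0.728 against 1.350 in the batch listed from 5 reads and -0.337 against 0.414 in the other. The median interaction of the 104 with Thiamet-G was 0.062 (camera with a preset correlation, adjusted p = 0.535).

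Starvation also lowered the footprint level of some transcripts among ribosomes associated with eIF3. Across the 8 eIF3-80S libraries, with background as an additive term, 22 of 7734 transcripts fell and limma called 0 higher, with 648 at an unadjusted p under 0.05. The median log2 fold change of all 7734, most of which were not listed in every file, was -0.75, and leaving out any 1 library reduced the 22 calls to between 0 and 2. Quantile normalization gave 14 lower and 9 higher, 7 of them shared with the 22, and eBayes without a trend gave 23 lower that shared none. Among the 1679 transcripts listed in every library, where the median was 0.025, 104 fell and 76 rose, and the 104 included all 22. This restriction leaves out transcripts that fell below 5 reads in a library. Limma-voom on recovered reads called 105 lower and 80 higher. The 104 had a median coding length of 615 nt, a median Ribo-seq level of 1243 RPKM and a median log2 fold change of -1.20, and the 76 had a median of 1600.5 nt, 78.6 RPKM and 1.20. Coding regions of at most 600 nt made up 48 of the 104 (46.2%) and 6 of the 76 (7.9%), against 18.0% of the 1679 (Fisher's exact test, adjusted p = 1.67e-11 and 0.0171), while 89.45% of random lists matched on level held as large a share as the 104, and the share of the 76 lay inside the 5.3% to 15.8% of its matched lists. In control cells alone limma called 0 of 7734, with 566 at an unadjusted p under 0.05, and limma-voom 0, but quantile normalization gave 112 calls, eBayes without a trend 277, and leaving out 1 library 3 to 1368.

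Calls of both assays overlapped although no library was shared. Of 1677 transcripts tested in both, 16 were called lower in Ribo-seq and all 16 were among the 104 called lower in eIF3-80S-seq, where independent lists would share 0.99 (Fisher's exact test, p = 1.52e-20). Fisher's test takes transcripts as independent and equally likely to be called, so its p overstates the agreement of lists of highly read transcripts. Random lists matched on level also fell in eIF3-80S control replicate 1, with medians mostly from -1.334 to -0.304, against -1.519 for the 16. For the 16 in eIF3-80S-seq, camera gave an adjusted p of 4.08e-17 with a preset and 0.0779 with an estimated correlation. With the batch as a block in Ribo-seq, 36 of 48 lower calls were shared, against 2.98 for independent lists, and 4 of 12 higher calls were shared with the 76, against 0.54 (Fisher's exact test, p = 2.12e-36 and 0.00146). In the averaged Ribo-seq contrast, 74 of the 104 were below 0 (median -0.59) and 68 of the 76 above 0 (median 0.59; camera with a preset correlation, adjusted p = 3.55e-20 and 1.1e-13; adjusted p = 0.33 and 0.277 with an estimated correlation).

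**Figure D3:**
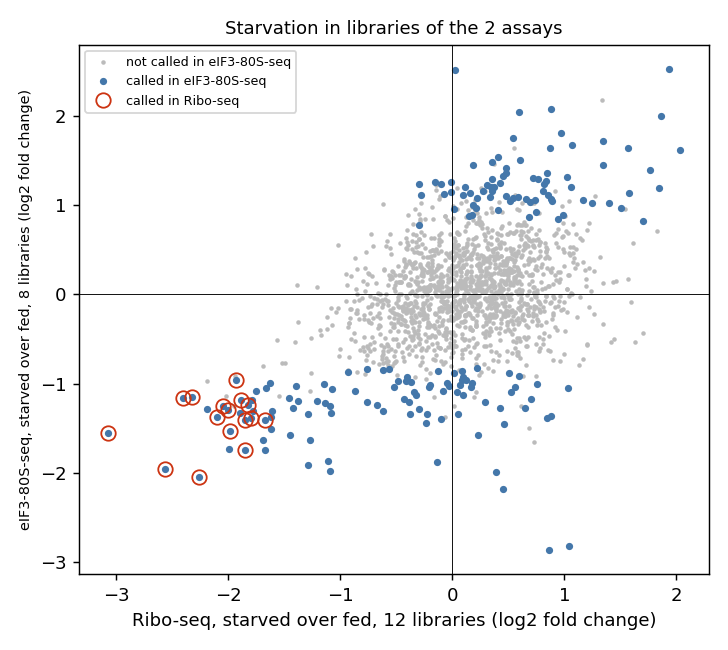
Log2 fold change of starved over fed in eIF3-80S-seq (vertical axis, 8 libraries) against the average over backgrounds in Ribo-seq (horizontal axis, 12 libraries) for 1677 transcripts, 1 point each. Blue points are the 180 called in eIF3-80S-seq, and red circles mark the 16 called in Ribo-seq, all 16 of which lie below 0 on both axes.

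Single eIF3-80S libraries of knockout and Thiamet-G cells had no replicate check. The 19 transcripts that fell in Ribo-seq had a median log2 ratio of starved to fed of -1.04 in knockout and -1.53 in Thiamet-G cells. For the 16 of them listed in every eIF3-80S library the medians were -1.04 and -1.47, with 16 of 16 below 0 in both and 0.87% and 0.00% of 10000 random lists matched on level and coding length lying lower. In fed cells the same 16 had a median of -0.19 for knockout over control and 0.092 for Thiamet-G over control, at the 16.2 and 83.27 percentiles of such lists. The 48 listed transcripts among the 79 called with the batch as a block had medians of -0.229, with 36 of 48 below 0, and 0.063, at the 1.37 and 79.2 percentiles. Of 1679 transcripts, 158 and 169 differed at least 2-fold between fed knockout and each single fed control library, and 196 and 70 between fed Thiamet-G and each, against 205 between the replicates of fed control cells. The share of reads on coding regions of at most 600 nt was 19.4% ± 0.66 in fed and 15.8% ± 2.48 in starved eIF3-80S libraries (n = 4 each, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0381). It was lower in 4 of 4 starved libraries, with a difference of -4.12 points and exact permutation p = 0.114 once the most read transcripts were left out.

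Finally, footprints of eIF3-associated ribosomes were set against all footprints in fed control cells, to ask which transcripts they over-represented. The assays also differed in the range of fragment sizes selected. Long coding regions held a larger share of listed reads in eIF3-80S-seq. Those over 3000 nt took 23.4% ± 5.24 of reads in eIF3-80S (n = 8) and 7.45% ± 1.55 in Ribo-seq (n = 12) across all groups (exact permutation p = 7.94e-06, the smallest possible), and those of at most 600 nt took 17.6% ± 2.54 and 30.1% ± 6.82 (exact permutation p = 0.000111). Reads on unlisted transcripts, 3.27% to 32.6% of eIF3-80S totals and 0.04% to 2.72% of Ribo-seq totals, did not enter these shares. The eIF3-80S library with 32.6% unlisted had 30.17% over 3000 nt, and that with 3.27% had 18.1%. Depth and listing were not matched between the assays, so they may account for part of the differences. A few transcripts also carried part of both differences. Without the 69 transcripts among the 10 most read of any library, the shares over 3000 nt were 15.9% ± 1.97 and 7.98% ± 1.65, so the difference fell from 15.98 to 7.91 points (exact permutation p = 7.94e-06), and that of the short class from -12.48 to -8.81 points (exact permutation p = 0.00168). Limma called 45 of 10542 transcripts higher and 2532 lower, but 2432 (96.1%) of the lower ones were not listed in a fed control eIF3-80S file, and the median log2 fold change of all transcripts was -1.72. Limma-voom called 21 higher and 0 lower, with 1006 of 9302 at an unadjusted p under 0.05, and quantile normalization gave 151 higher and 306 lower with a median of 0.169. Among the 1675 listed in every library, 28 were higher, 17 of them with coding regions over 3000 nt (60.7%, against 15.3% of the 1675; Fisher's exact test, adjusted p = 6.41e-08), and 36 were lower, 27 of them of at most 600 nt (adjusted p = 2.25e-13). Of 10000 random lists matched on eIF3-80S level, 0.00% reached either share. Ribo-seq level was not matched, and its median was 11.2 RPKM for the 28 and 891.8 RPKM for the 36. These lists therefore do not separate coding length from Ribo-seq level. ENSMUST00000130864, with a coding length of 4920 nt, had 15527 ± 20467 RPKM in eIF3-80S and 4.62 ± 1.73 RPKM in Ribo-seq (n = 2 each), a log2 fold change of 10.0 (SE 1.64, limma adjusted p = 0.00119; limma-voom adjusted p = 0.454), and 7.60 to 12.4 with 1 library left out. ENSMUST00000110603, with a coding length of 1869 nt, had 4058 ± 2823 and 5.72 ± 0.542 RPKM (n = 2 each), a log2 fold change of 9.04 (SE 1.01, limma adjusted p = 0.000181), and 8.27 to 9.82 with 1 library left out. Of the starvation changes in control cells, 93 transcripts differed between assays, 2 with a more positive and 91 with a more negative change in eIF3-80S-seq, and all 91 were missing from both starved control eIF3-80S files. Without a difference, 50.5% of the values missing for those 91 would have been expected under 5 reads, so low depth and a real decrease could not be told apart. The 1675 transcripts listed in every library held none of the 93, and limma called 0 differences among them, with 107 at an unadjusted p under 0.05, while limma-voom called 0 of all transcripts.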

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

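The tests of unlisted transcripts and limma-voom in this part were chosen after the result was seen, while the interaction itself was planned. The effect of starvation in control cells differed between assays for 93 of 10542 transcripts, by a test of the difference itself, and this was the result that called for a closer look. The number was unstable, with 1 call under quantile normalization or array weights, 3 with a pseudocount of 5, and 0 to 1627 with 1 library left out (limma; 464 to 592 at an unadjusted p under 0.05 in the 3 fits with 0; limma-voom 0). Of 16 groups of libraries examined for a single library far from the others, 0 held one. A group of 2 libraries cannot show which of them is apart, however. The 2 starved control eIF3-80S libraries listed 1919 and 4864 transcripts.

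Transcripts that a file does not list may account for part of this result and of the 2532 transcripts called lower in eIF3-80S-seq than in Ribo-seq. Of those 2532, 96.1% were missing from a fed control eIF3-80S file, and all 91 with a more negative starvation change in eIF3-80S-seq were missing from both starved control files. The restriction to transcripts listed in every library tests nothing here, because it leaves out all 93 by construction. Reads expected without a difference were therefore calculated for each missing value. They were under 5 for 64.9% of the values missing among the 2532, expected from Ribo-seq, and for 50.5% of those missing among the 91, expected from fed eIF3-80S and the Ribo-seq change. Depth thus neither covers nor excludes either pattern, and unlisted transcripts cannot be told apart from lower levels. The starved control eIF3-80S libraries had 52148 and 129252 reads, against 1505367 or more for starved control Ribo-seq. A biological difference between assays was not excluded for these transcripts, since a transcript below 5 reads has no level in the eIF3-80S files.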

How the results depend on the processing

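Limma-voom, the uniform floor of 5 reads, the restriction to listed transcripts combined with a block, the fit without Thiamet-G libraries the alternatives for length classes and the sign flips within pairs were chosen after the results were seen, and the other settings were planned. The eIF3-80S files, of 52148 to 359282 reads, hold no level for a transcript under 5 reads. The cause of a change was not tested, except that fewer transcripts or libraries enter some settings by construction. The fed contrasts of knockout and of Thiamet-G with control, starvation in knockout cells and the Thiamet-G interaction stayed at 0 calls by limma in every setting run, with 401, 51, 99 and 145 transcripts at an unadjusted p under 0.05.

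The 19 Ribo-seq starvation calls became 0 under quantile normalization, a pseudocount of 0.1, no filter, eBayes without a trend, the uniform floor and without Thiamet-G libraries (974, 988, 1067, 870, 963 and 535 at an unadjusted p under 0.05; limma-voom 49), and 34 among transcripts listed in every library. With a replicate block they became 100 for file-name numbers, which follow the batch, and 7 for title numbers. The file-name block gave 63 with the uniform floor, 104 among listed transcripts and 380 in limma-voom (257 higher, 123 lower), all 19 among each. Leaving out each library gave 0 to 25 calls, and 9 of the 12 fits gave 0 (781 to 1236 at an unadjusted p under 0.05). It was 0 without either fed control, fed Thiamet-G or starved Thiamet-G library, or replicate 1 of starved control, fed knockout or starved knockout, and 10 without starved knockout replicate 2. In other Ribo-seq contrasts with 0 calls (744, 642, 653 and 216 at an unadjusted p under 0.05), limma-voom with the file-name replicate block called 220 for starvation in control cells, 21 for knockout against Thiamet-G, 13 for starvation in Thiamet-G cells and 1 for the knockout interaction. The first became 9 among listed transcripts with that block, and neither replicate block alone changed these 0 calls. Title numbers did not pair the libraries (correlations of -0.394 to 0.453; 0.037 in eIF3-80S-seq).

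For eIF3-80S starvation in control cells, 0 calls (566 at an unadjusted p under 0.05) became 112 under quantile normalization, 5 among listed transcripts and 277 without a trend, and stayed 0 with the title replicate block and in limma-voom. Leaving out a library gave 3 (starved replicate 2) to 1368 (fed replicate 1), with 336 without fed replicate 2 and 248 without starved replicate 1. The 22 calls over backgrounds became 2 on RPKM as deposited, 12 at a mean of at least 10 RPKM, 180 among listed transcripts, 48 with array weights, 4 with the title replicate block and 185 in limma-voom. Each left-out library lowered them, to 0 to 2. Quantile normalization (14 lower, 9 higher) shared 7 of the 22, and no trend (23 lower) none.

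The 2577 calls between assays became 457 (151 higher and 306 lower) under quantile normalization, 1635 with a pseudocount of 5, 1598 at a mean of at least 10 RPKM, 64 among listed transcripts, 21 in limma-voom and 35 in limma-voom with the file-name replicate block, all higher, and 214 among listed transcripts with it. The file-name block alone gave 2921 and left-out libraries 1459 to 2960, with 1695, 1459 and 1542 without fed control Ribo-seq replicate 1, replicate 2 and eIF3-80S replicate 1. The 93 interaction calls became 165 on RPKM as deposited, 1 under quantile normalization, 357 and 3 with pseudocounts of 0.1 and 5, 147 at a mean of at least 10 RPKM, 1 with array weights, 26 with the title replicate block, 105 with the file-name block (90 of them shared), and 0 among listed transcripts, which hold none of the 93 by construction (107 at an unadjusted p under 0.05), in limma-voom (120), and in both with the file-name block (146 and 235). Leaving out libraries gave 0 (fed control Ribo-seq replicate 2 or either starved one) to 1627 (starved eIF3-80S replicate 2), with 22 without fed Ribo-seq replicate 1 and 277 without starved eIF3-80S replicate 1.

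The median ratios of the 19 transcripts in single eIF3-80S libraries, -1.04 for knockout and -1.53 for Thiamet-G, became -0.53 and -1.12 under quantile normalization, and the latter -1.80 on RPKM as deposited. The -8.38 points on short coding regions in Ribo-seq ranged from -10.2 to -6.56 with 1 library left out. With a replicate block, as sign flips within pairs of one background and batch, the size stayed at -8.38 and exact p became 0.0625. The -3.56 points in eIF3-80S-seq became -1.79 for at most 450 nt (exact p = 0.0571) and -4.12 without the most read transcripts (exact p = 0.114), and ranged from -4.26 to -2.36 with 1 library left out, where exact p was 0.0571 without any 1 fed library. Between assays, 15.98 points over 3000 nt became 7.91 and -12.48 at most 600 nt became -8.81 without the most read transcripts, with ranges of 15.02 to 16.76 and -13.29 to -11.27 with 1 library left out. All alternatives of the gene lists, the row choice per gene and the estimated correlation for those lists were not run, since identifiers were not paired with names. No paired analysis was possible for single eIF3-80S libraries because they carry 1 number.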

Other observations

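Except for the test of depth, the tests in this part were chosen after the results were seen. Starvation ratios correlated between eIF3-80S comparisons and, less uniformly, between Ribo-seq batches. Over 1679 transcripts, which are not independent replicates, log2 ratios of starved to fed correlated at r = 0.416 to 0.461 (Spearman's rho 0.377 to 0.44) for all 6 pairings of the 4 eIF3-80S comparisons, knockout included. Between the 2 Ribo-seq batches, which share no library, they correlated over 7316 transcripts at r = 0.227 in control, 0.245 in Thiamet-G and -0.145 in knockout cells (rho 0.252, 0.285 and -0.144). The eIF3-80S ratios correlated with the mean Ribo-seq ratio at r = 0.283 to 0.376 over 1603 transcripts (rho 0.211 to 0.311).

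Ratios of fed knockout to fed control in Ribo-seq were compared with starvation. Across batches without a shared library, they correlated with control starvation at r = 0.177 and 0.218 (rho 0.219 and 0.246), and the ratio of fed Thiamet-G to fed control at r = -0.043 and -0.086 (rho -0.063 and -0.09). A fed knockout that resembles starvation is a hypothesis, consistent with the medians of the 19 starvation-lowered transcripts in both batches, of which -1.319 was the one closer to 0. An offset between processing batches cancels by design in ratios taken within a batch, so these medians do not test it. A difference that depends on the batch cannot be told apart as a cause, because the 19 were chosen on the same control libraries, and the 104 chosen in eIF3-80S-seq had upper quartiles of 0.66 and 0.02 in the batches. Each batch holds 1 fed knockout and 1 fed control library, so a difference of single libraries was not tested. Per the labels only knockout cells had 4-OHT and fresh medium, so that treatment cannot be told apart from the loss of Ogt. Random lists matched on level and coding length were lower in 3.52% of draws in the batch listed from 5 reads and 0.00% in the other. Selection of the transcripts on the same control libraries stayed open. The 104 transcripts chosen in eIF3-80S-seq lay at percentile 49.53 of such lists in the batch listed from 5 reads and at 0.00 in the other. The 76 called higher there had medians of 0.449 and 0.487, at percentiles 95.93 and 99.97. In eIF3-80S-seq the 16 listed transcripts had a median of -0.19 for fed knockout over control, at the 16.2 percentile, and the 48 listed transcripts of the batch-block list had -0.229, at the 1.37 percentile, from 1 knockout and 2 control libraries.

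The lower share of starved Ribo-seq reads on short coding regions was weighed against technical explanations. A few dominant transcripts were excluded as the whole cause by leaving out 44 of them (-7.64 points, exact p = 0.0303). A batch effect that depends on the state stayed open. The batches hold both states equally, so an offset between them cancels by design, and permuting within batches gave exact p = 0.025. Sign flips within pairs of one background and batch gave exact p = 0.0625, where 0.0312 was the smallest possible. They test the consistency of the pairs and not a batch effect. The difference in the batch with many transcripts under 5 reads, -3.63 ± 5.37 points, did not exceed its spread. Library depth stayed open too. Thinning each library to 844033 reads with a floor of 5 reads gave -8.42 points (plain thinning -8.37), yet random thinning leaves the expected share of a library unchanged, so the bound written beforehand for this test was wrong by design and the test decides nothing. Amino-acid starvation may lower this share, and the other assay changed in the same direction (exact p = 0.0286). Also open are recovery of fragments that depends on coding length and varied with the state (no value decides; -8.38 points), and the level of the transcripts instead of their length, since 72.11% of lists matched on level had as large a share as the 19 and 0.25% as the 79. Fold changes also followed coding length far more closely in one batch, with Spearman's rho across transcripts of 0.483 against 0.099 for control starvation and 0.501 against 0.07 for fed knockout over control.

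Other splits of the libraries bear on the starvation calls. In an additive Ribo-seq fit, 4 of 100 of the 462 splits of 6 against 6 libraries gave as many calls as the real 31, which are not the 19 of the averaged contrast. The real split balances the batches and the others need not, so this rank cannot exclude chance. The highest other split gave 243 and held 5 of the 6 libraries of one batch in one of its groups, and a split by batch itself gave 931. Unlisted transcripts entered as 0, so the listing that defined the batches may add to the 931. In these values the batch was the stronger structure. With it as a term 1 of 100 splits, the real one with 74 calls, gave as many, against 43 for the highest other. For the 22 eIF3-80S calls chance was not excluded, since 5 of the 34 splits that could be fitted, of 35, gave as many and the highest other gave 263, a structure that parts the 4 shallowest libraries from the deeper ones. Among transcripts listed in every library 1 of 34 did, the real split with 180 calls against 4. Sharing of 16 calls between assays, with Fisher's exact p = 1.52e-20, fits a change of the same transcripts in both, but that test takes transcripts as independent. Camera with an estimated correlation gave the 16 an adjusted p of 0.0779 in eIF3-80S-seq.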
